A study of Mus musculus with 6 samples.

How the data were processed

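Total RNA from the cremasteric sac of male mice was profiled on Illumina bead arrays, with 1 array for each of 3 wild-type and 3 cryptorchid transgenic samples. Per the labels' protocols, RNA was extracted with Trizol, cleaned on a spin column with DNase I treatment, checked on a Bioanalyser and copied into biotinylated cRNA with an Ambion amplification kit. The software, the background method and the normalization behind the deposited values are not given in the sources used here. The deposited table holds probe intensity on a linear scale, and 30.6% of its values lie below 0, from −26.3 to 35167.8, as after subtraction of a background. The sorted values of the 6 arrays nearly coincide, and the array medians run from 6.92 to 6.98, as after quantile normalization. The size of the subtracted background stays unknown. A further table with 12 columns of intensities and detection p-values was not used here, because its column names match no single sample.

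The deposited intensity values were corrected with the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, quantile normalized again and taken to log2. The offset compresses the fold changes of dim probes. The design fixed before the data were examined named this step for a table without control probes or detection p-values, and named a filter on detection p-values, which had no usable column. In its place, a probe was kept when its intensity lay above a noise threshold on at least 3 of the 6 arrays. The threshold, on average 11.3 intensity units, is the 95th percentile of noise symmetric about 0, read from the values below 0. Of 45281 probes, 34885 carry 1 gene symbol in the platform annotation, 18 carry several and 10378 carry none. Entrez identifiers of 34807 probes were found in a RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols needed an update. The filter kept 19188 probes. Each symbol was represented by its brightest kept probe, and probes without a single symbol stayed as features of their own, named by probe only. This gave 13694 features, 10880 of them with a symbol, which are called genes here.

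Groups were compared with limma's linear model and moderated test, fitted to all 6 arrays without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of fold changes are standard errors (SE) from this fit with n = 3 arrays per group, and group means carry the SD. In all, 45 gene lists holding 1205 symbols were fixed before the data were examined, and 2 of the symbols matched no gene of the table. The 44 lists with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. For a gene that lay below the noise threshold on every array of a group, the fold is a bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes above noise and the probe's own signal.

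The genes named in the text were chosen by a rule fixed beforehand. They include Rxfp2, the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, at most 6 members of each described list past the threshold (or the 3 of smallest p where none passed), and Ctnnb1, Notch1, Notch2, Notch3, Hes1, Hey1, Heyl, Rbpj, Axin2 and Lef1 whatever their p. Clone names and predicted genes were left out of the largest changes. Genes named outside this rule are said to be so.

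The procedure was tested on simulated data with 13694 features and 200 changed genes in each of 5 draws. For the comparison of cryptorchid with wild type, 88.8% of changes of 1 on the log2 scale and 37% of changes of 0.5 were recovered, with 25 false calls over the 5 draws. A list shifted by −0.3 was found by camera in 5 of 5 draws, and 0 of 205 tests of other lists passed. These simulations drew genes independently of each other. The number of arrays limits the precision. Since the labels do not say whether the replicates are separate animals, p-values measure only the spread between these samples, which may be technical. Array positions, chip numbers and dates were not used here. Alternatives for the background step, the normalization, the filter, the choice of probe, the variance model, array weights, a replicate block and the arrays included were computed, and their effects are given in the closing section.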

Results

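Gene expression was measured in the cremasteric sac, the pouch of cremaster muscle and connective tissue that develops from the gubernaculum and holds the descended testis. The 6 samples came from male mice of 1 month of age and a mixed strain background, 3 of them wild type and 3 cryptorchid, with undescended testes. Per the sample labels, the cryptorchid males carried a transgene for a short hairpin RNA against Rxfp2, the receptor of the testicular hormone INSL3, while the design text of the series names Rxfp1. The series asks what suppression of the INSL3 receptor does to β-catenin and Notch signalling in the gubernaculum. Each array had between 19181 and 19226 of its 45281 probes above the noise threshold. As the sorted values of the 6 arrays nearly coincide, these counts had to be alike and do not measure sample quality. Pearson correlations over all tested genes lay between 0.985 and 0.992 within groups and between 0.973 and 0.987 across groups.

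Rxfp2, the hairpin's target, had a log2 fold change of −0.64 ± 0.27 (SE) in cryptorchid against wild type, with a mean log2 intensity of 7.56 ± 0.55 (SD, n = 3) against 8.20 ± 0.45 (SD, n = 3). It did not pass the test (limma, adjusted p = 0.187). With a block for replicate number, a pairing that the labels do not state, the same change had an adjusted p of 0.0296 by limma. The linear intensities of this probe were 248.2, 315.6 and 141.9 on the wild-type arrays and 69.1, 219.5 and 105.1 on the cryptorchid arrays, so the groups overlapped. The dimmer second Rxfp2 probe had a log2 fold change of −0.09 ± 0.11 (SE). Rxfp1, the relaxin receptor, had a log2 fold change of 0.16 ± 0.16 (SE), and Insl6 one of 0.41 ± 0.18 (SE), with adjusted p-values of 0.599 and 0.219. The INSL3 and relaxin family list, with 3 measured members, did not shift (camera adjusted p = 0.811).

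Genes of blood vessel endothelium were among the largest falls in the cryptorchid sac. Plvap, a protein of the endothelial diaphragm, fell by 1.23 ± 0.19 (SE) on the log2 scale, and Vwf, the von Willebrand factor, fell by 1.20 ± 0.22. Flt1, a receptor of vascular endothelial growth factor, fell by 1.03 ± 0.19, and Col4a2, a collagen chain of basement membranes, fell by 0.98 ± 0.13. The rises included H2A histone genes led by H2ac15, which rose by 1.24 ± 0.17 on the log2 scale, and Lipa, the lysosomal acid lipase, which was above noise on all 3 cryptorchid arrays and on 0 of the wild-type arrays. In all, 595 of 13694 genes and unnamed probes changed between the groups (limma, Benjamini-Hochberg adjusted p under 0.05), 260 of them higher and 335 lower in cryptorchid. Changes of at least 2-fold were found for 20, of which 8 were higher and 12 lower, and the median fold of the changed genes was 1.44. At an unadjusted p under 0.05 there were 3093. The adjusted count was 0 without wild-type replicate 3, 7 without cryptorchid replicate 2, 14 without cryptorchid replicate 1 and 56 without wild-type replicate 2. This count was 549 without wild-type replicate 1 and 520 without cryptorchid replicate 3. It was 0 where values under the noise threshold were set to it and 13 with a background offset of 16.

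**Figure D1:**
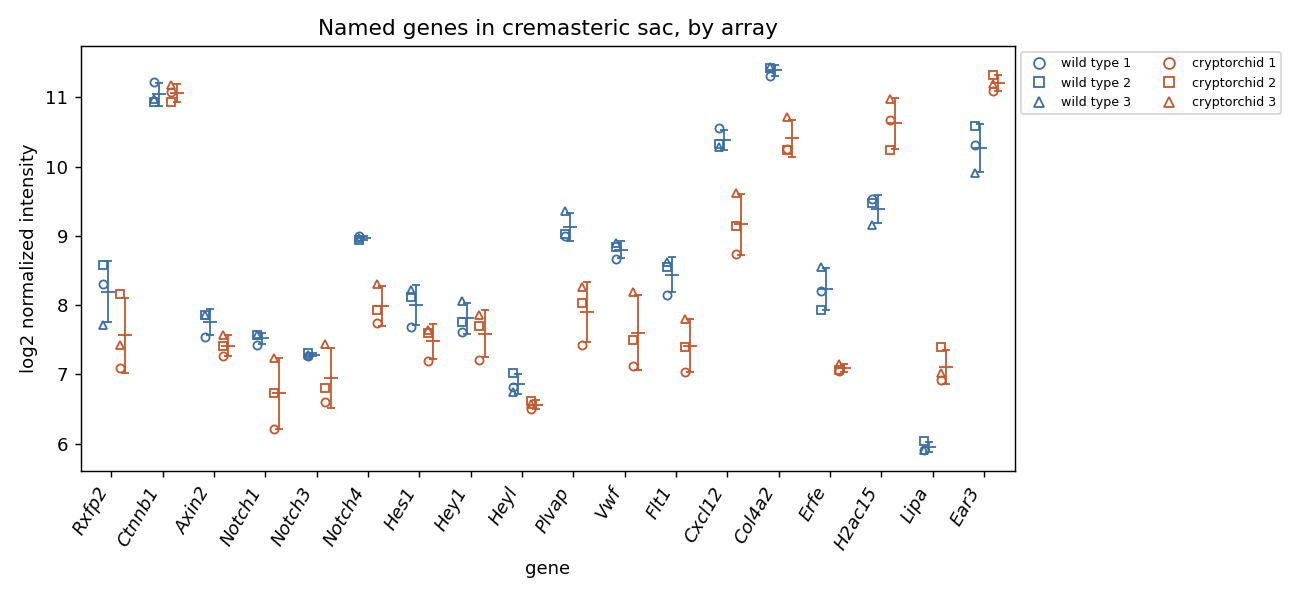
Log2 normalized intensity of 18 named genes on the 6 arrays, with the gene on the horizontal axis; open symbols are single arrays of wild type (blue) and cryptorchid (orange), and the bars give the group mean ± SD with n = 3. Rxfp2 and Ctnnb1 overlap between the groups, while Plvap, Vwf, Flt1 and Notch4 are lower and H2ac15, Lipa and Ear3 higher on every cryptorchid array than on any wild-type array. Of these, all but Rxfp2, Ctnnb1 and Notch4 were chosen among genes whose groups do not overlap.

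The 12 largest falls among genes without overlap of the groups ran from Plvap to Col4a2. Among them were Cxcl12, a chemokine of stromal cells, which fell by 1.22 ± 0.19 (SE) on the log2 scale, Smoc1, a matrix protein that binds BMP signalling components, which fell by 1.18 ± 0.18, and Erfe, the muscle and erythroid hormone erythroferrone, which fell by 1.14 ± 0.14. For Cxcl12 the other 2 kept probes did not move alike, with log2 fold changes of 0.04 and −0.18, and the second probe of Smoc1 gave −0.13. Aoc3, an amine oxidase of vessel walls and adipocytes, fell by 1.07, Uchl1, a neuronal ubiquitin hydrolase, by 1.05, and Plin4, a lipid droplet protein, by 1.01. Rgma, a BMP co-receptor, and Snai3 each fell by 1.00, with adjusted p-values of 0.0143 and 0.0412. In the fixed lists, Pnpla2, the adipose triglyceride lipase, fell with Plin4 among 15 adipocyte markers, and 13 did not pass.

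Of the 22 measured endothelial markers, 7 fell, 0 rose and 15 did not pass, with a median log2 fold change of −0.36. Adjusted over the list alone, 12 fell. Sox18, an endothelial transcription factor, fell by 0.72 ± 0.11 (SE) on the log2 scale, Robo4 fell by 0.84 ± 0.16 and Eng, a co-receptor for TGF-β ligands, fell by 0.75 ± 0.16. The list shifted down (camera adjusted p = 7.79e-06), with an adjusted p = 0.434 with an estimated correlation. Among 21 smooth muscle and pericyte markers, 4 fell, 0 rose and 17 did not pass, and adjusted over the list alone 7 fell and 2 rose. Myh11, the smooth muscle myosin, fell by 0.68 ± 0.13, Actg2 by 0.67 ± 0.13 and the potassium channel gene Kcnj8 by 0.50 ± 0.10. Des, which is also in the list of sarcomere structure, fell by 0.46 ± 0.10. Named outside the rule, Rgs5 and Kcnmb1 were the 2 that rose over the list alone, by 0.44 and 0.27. Acta2, Cald1 and Tagln, also outside the rule, had log2 fold changes of 0.007, 0.06 and 0.13. Of all members, 15 values lay below 0 and 6 above. This list shifted down (camera adjusted p = 0.00963), with an adjusted p = 0.434 with an estimated correlation.

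Among 37 collagens and matrix proteins, 7 fell, 0 rose and 30 did not pass, and 9 fell when adjusted over the list alone. Beside Col4a2, these included Bgn, the small proteoglycan biglycan, which fell by 0.76 ± 0.13 (SE) on the log2 scale, Eln, elastin, which fell by 0.56 ± 0.09, and Col5a1 and Col6a2, which fell by 0.60 ± 0.11 and 0.67 ± 0.14. The second kept probe of Eln had a log2 fold change of −0.08. The list shifted down (camera adjusted p = 0.00222), with an adjusted p = 0.471 with an estimated correlation. Among 33 genes of IGF, FGF and other growth factor signalling, 6 fell, 0 rose and 27 did not pass, with 8 falling when adjusted over the list alone. Igf2, an insulin-like growth factor of fetal and juvenile tissue, fell by 0.49 ± 0.10, Fgf10, a mesenchymal growth factor, by 0.59 ± 0.13 and Pdgfb, which recruits pericytes, by 0.58 ± 0.10. The list's camera adjusted p was 0.00963, with an adjusted p = 0.434 with an estimated correlation. Of the fibroblast markers, Dpp4 rose by 0.70 ± 0.14 and Mfap5 by 0.53 ± 0.13. Serpinf1 fell by 0.50 ± 0.10, with 0.00473 for its second kept probe, and the list of 20 did not shift (camera adjusted p = 0.163).

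Of the Notch pathway, 32 members were measured, of which 2 fell, 0 rose and 30 did not pass. Notch4, a receptor found mainly on endothelium, fell by 0.98 ± 0.14 (SE) on the log2 scale, from a mean log2 intensity of 8.97 ± 0.03 (SD, n = 3) to 7.99 ± 0.29 (SD, n = 3). Neurl1a, a ubiquitin ligase that acts on Notch ligands, fell by 0.65 ± 0.11, while its second probe had a log2 fold change of −0.04. Notch1 had a log2 fold change of −0.79 ± 0.20 (adjusted p = 0.0563), and the target gene Hes1 one of −0.53 ± 0.16 (adjusted p = 0.0859). The values were −0.34 ± 0.18 for Notch3, −0.22 ± 0.17 for Hey1 and −0.30 ± 0.10 for Heyl, and these did not pass either. Adjusted over the list alone, 7 members fell. The list shifted down with a median of −0.17 (camera adjusted p = 0.00222), with an adjusted p = 0.471 with an estimated correlation. Its mean log2 deviation was −0.20, −0.10 and −0.01 on cryptorchid replicates 1, 2 and 3, against 0.03 to 0.14 on the wild-type arrays. Probes for Notch2, Rbpj and Lef1 did not pass the noise filter.

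Ctnnb1, which encodes β-catenin, had a log2 fold change of 0.02 ± 0.11 (SE, adjusted p = 0.943), with a 95% interval from −0.23 to 0.27. Its 3 other kept probes gave 0.13, 0.32 and 0.03. Of 25 measured β-catenin core and target genes, 0 rose and 0 fell, also when adjusted over the list alone. Axin2, a feedback target of β-catenin, had a log2 fold change of −0.33 ± 0.12 (adjusted p = 0.139), and the 3 of smallest p were the co-activator gene Bcl9l with −0.44 ± 0.11, Sox9 with −0.38 ± 0.11 and Pygo2 with −0.34 ± 0.10. The list's median was −0.12, with 19 values below 0 and 6 above. It shifted down (camera adjusted p = 0.0372), with an adjusted p = 0.471 with an estimated correlation, and the call was lost in 9 of 20 alternatives, where the adjusted p reached 0.5. Among 30 Wnt ligands, receptors and modulators, Fzd7, a frizzled receptor, fell by 0.43 ± 0.10, 29 did not pass and the list did not shift (camera adjusted p = 0.163). Among 34 genes of BMP and TGF-β signalling, 0 passed, and Acvr2b had the smallest p with a log2 fold change of −0.42 ± 0.11. Among 15 Hox and limb or urogenital patterning genes, Tbx4, a hindlimb transcription factor, fell by 0.53 ± 0.12, and the list shifted down (camera adjusted p = 0.00963), with an adjusted p = 0.434 with an estimated correlation.

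Skeletal muscle genes were measured as several lists. Of 21 genes of sarcomere structure and excitation coupling, 5 fell, 0 rose and 16 did not pass, and all 21 values lay below 0. Ryr1, the calcium release channel of the sarcoplasmic reticulum, fell by 0.80 ± 0.19 (SE) on the log2 scale, Sypl2, a triad protein, by 0.57 ± 0.09, Actn2, α-actinin of the Z-disc, by 0.48 ± 0.12 and Des, desmin, by 0.46 ± 0.10. Other kept probes gave from −0.61 to −0.15 for Ryr1 and −0.15 and −0.65 for Actn2. Adjusted over the list alone, 9 fell. The list shifted down (camera adjusted p = 2.17e-06), with an adjusted p = 0.434 with an estimated correlation. In the slow contractile list, Myl3, a slow myosin light chain, fell by 0.94 ± 0.18 and Myom3 by 0.78 ± 0.13, 16 others did not pass, and the list did not shift (camera adjusted p = 0.0553). In the fast contractile list, Mylk2, Myh1 and Myoz3 fell by 0.64, 0.44 and 0.44, and 20 others did not pass (camera adjusted p = 0.096). None of 16 myogenic regulators passed, and Myod1, the muscle determination factor, had a log2 fold change of −0.43 ± 0.12. That list shifted down (camera adjusted p = 0.0182), with an adjusted p = 0.434 with an estimated correlation, and 3 members fell when adjusted over the list alone. None of 16 muscle atrophy genes passed, and the list did not shift (camera adjusted p = 0.425).

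Metabolic genes of muscle that passed were lower in cryptorchid. Pfkm, the muscle phosphofructokinase, fell by 0.67 ± 0.13 (SE) on the log2 scale among 25 glycolysis and glycogen genes, whose list shifted down (camera adjusted p = 0.0244), with an adjusted p = 0.471 with an estimated correlation. Cpt1b, which carries fatty acids into mitochondria, fell by 0.53 ± 0.11 together with Ppard and Mlycd, which fell by 0.49 ± 0.11 and 0.46 ± 0.11, among 21 fatty acid oxidation genes (camera adjusted p = 0.073). None of 45 oxidative phosphorylation genes passed, and their median of 0.03 and mean of −0.01 differ in sign. Of 23 heat shock genes and chaperones, Bag3 fell by 0.81 ± 0.14 and Hspb1 by 0.67 ± 0.17, and the list did not shift (camera adjusted p = 0.327). The other 21 did not pass and 11 of the 23 values lay above 0, while 3 rose and 6 fell when adjusted over the list alone.

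The rises were led by histone genes and included 4 cell cycle genes. Of the 12 largest rises, 6 were H2A genes, H2ac15, H2ac12, H2ac22, H2ac7, H2ac24 and H2ac11, with log2 fold changes from 0.95 to 1.24. H2A paralogs have close sequences and the probes were not compared, so which of them rose, and how many, is uncertain. Lipa rose at least 1.76-fold (limma adjusted p = 0.0143), and its second probe also lay above noise on 3 of 3 cryptorchid and 0 of 3 wild-type arrays. Lipo3, another lipase gene of the same chromosome, rose by 0.89 ± 0.15 (SE) on the log2 scale, Ear3, a ribonuclease of eosinophils with close paralogs, by 0.94 ± 0.16, Uba6, a ubiquitin-activating enzyme, by 0.90 ± 0.18, Fam110c by 0.82 ± 0.17 and Hamp2, a hepcidin paralog, by 0.79 ± 0.15. Of 29 cell cycle genes, 4 rose, 0 fell and 25 did not pass, and 7 rose when adjusted over the list alone. Tyms, thymidylate synthase, rose by 0.70 ± 0.13, Top2a, a topoisomerase of dividing cells, by 0.65 ± 0.14, Tk1, thymidine kinase, by 0.56 ± 0.12 and Rrm1, a ribonucleotide reductase subunit, by 0.52 ± 0.12. The second probes of Top2a and Tk1 gave 0.02 and −0.12. The list shifted up (camera adjusted p = 0.000144), with an adjusted p = 0.471 with an estimated correlation. Its mean log2 deviation overlapped between the groups, with 0.08, −0.14 and −0.31 on the wild-type arrays and 0.17, 0.02 and 0.18 on the cryptorchid arrays, and without wild-type replicate 3 the mean change was 0.15 against 0.24.

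Markers of immune cells moved in both directions. Aif1 and Fcgr3, both of macrophages, rose by 0.60 ± 0.11 (SE) and 0.51 ± 0.09 on the log2 scale, 18 other macrophage and monocyte markers did not pass, and 6 rose and 1 fell when adjusted over the list alone. The list shifted up (camera adjusted p = 0.0182), with an adjusted p = 0.549 with an estimated correlation, and its mean deviation overlapped between the groups (0.06 on wild-type replicate 1 and −0.02 on cryptorchid replicate 3). Oasl2, Gbp3 and Gbp2, which interferon induces, rose by 0.56, 0.54 and 0.49, with 0.12, 0.29 and −0.14 for their second probes, and the antigen presentation and interferon list of 26 did not shift (camera adjusted p = 0.073). The mast cell genes Kit, Tpsab1 and Gata2 fell by 0.47, 0.43 and 0.48, and 11 other granulocyte and mast cell markers did not pass (camera adjusted p = 0.418). Among 22 chemokines, cytokines and complement genes, Cxcl14 fell by 0.61 ± 0.10 and C7 by 0.49 ± 0.12 beside Cxcl12 (camera adjusted p = 0.425). The second probes of Cxcl14 and C7 gave −0.105 and −0.249. The other 19 genes did not pass and 13 of the 22 values lay above 0, while 5 rose and 3 fell when adjusted over the list alone. None of 10 lymphocyte markers passed.

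Both lists of surface layer markers shifted up under camera with the preset correlation, while 1 gene of the 2 lists rose. Of 8 keratinocyte markers, Krt14, a basal keratin, rose by 0.59 ± 0.13 (SE) on the log2 scale, 7 did not pass, and the camera adjusted p was 0.0372, with an adjusted p = 0.471 with an estimated correlation. The call of this list was lost in 11 of 20 alternatives. Its mean log2 deviation was 0.34 and 0.12 on cryptorchid replicates 1 and 2, which had the highest Prm1, and −0.05 on cryptorchid replicate 3, against −0.06 on wild-type replicate 1. Of 17 mesothelium markers, 13 values were above 0, and the member that passed, Igfbp5, fell by 0.39 ± 0.10, while 4 others rose when adjusted over the list alone. The median of this list was 0.32 (camera adjusted p = 0.00963), with an adjusted p = 0.471 with an estimated correlation.

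**Figure D2:**
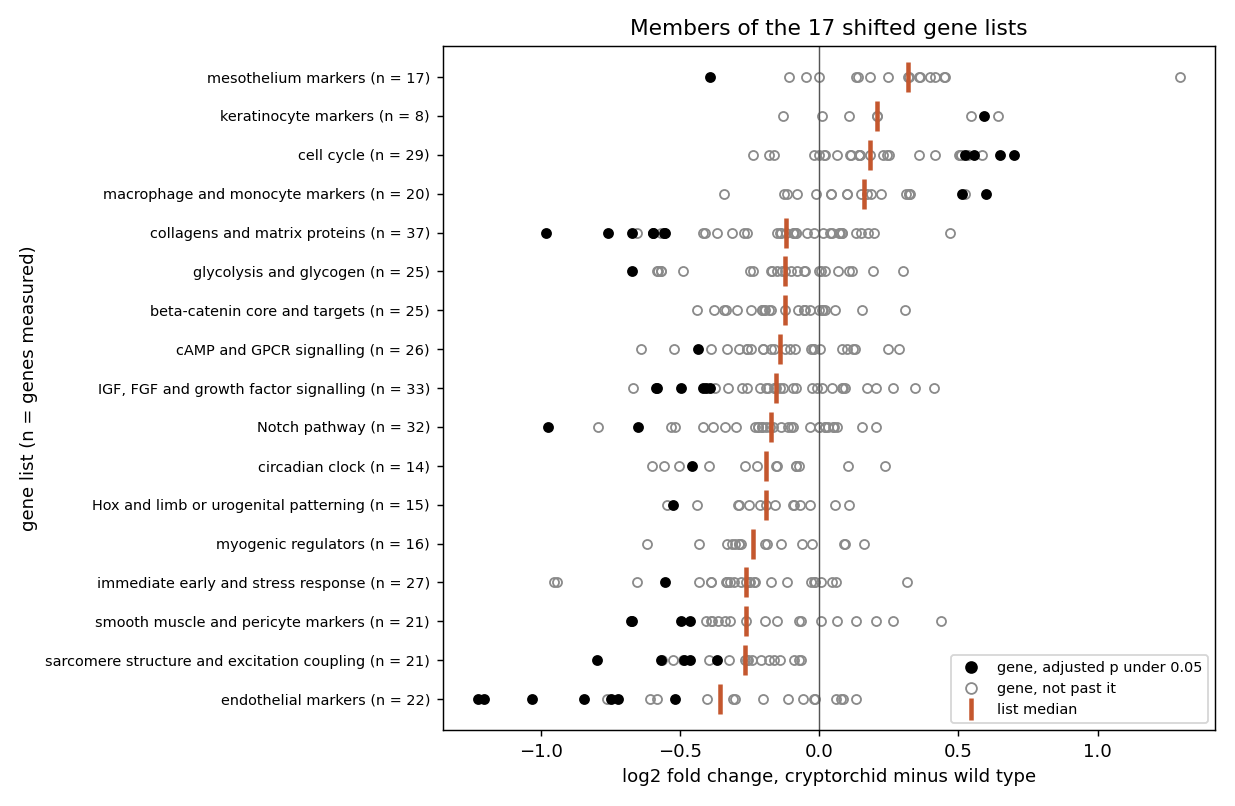
Log2 fold change, cryptorchid minus wild type, of each measured member of the 17 gene lists that shifted under camera with the preset correlation; each row is a list, filled points passed the adjusted threshold, open points did not, and the orange bar is the list median. The median is lowest for endothelial markers at −0.36 and highest for mesothelium markers at 0.32.

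Prm1, Gpx5, Spag11b, Ldhc and Cuzd1 were named after their values were seen, as markers of testis and epididymis. Prm1, a sperm protamine, had log2 intensities of 8.27, 7.003 and 7.59 on the wild-type arrays and 11.32, 11 and 6.59 on the cryptorchid arrays, with a log2 fold change of 2.02 ± 0.97 (SE, adjusted p = 0.25). Tnp1, a spermatid transition protein, followed the same arrays with 9.32, 9.14 and 6.24 in cryptorchid against 7.08, 6.39 and 6.57. Gpx5 and Spag11b, secretory genes of the epididymis, were highest on cryptorchid replicate 1 with 11.54 and 11.60 and ranged from 6.87 to 10.10 on the other arrays. Cuzd1 did not follow them, with an intensity of 2846 on wild-type replicate 1 and 2312 on cryptorchid replicate 1. None of 10 germ cell genes and none of 12 epididymis and vas deferens genes passed the test, and neither list shifted (camera adjusted p = 0.108 and 0.458). Cryptorchid replicates 1 and 2 thus carried the highest Prm1 levels, and endothelial markers lay lowest on the same arrays, at −0.38 and −0.23 of log2 deviation from the mean of 6 arrays, against −0.02 on cryptorchid replicate 3. With cryptorchid replicate 3 alone against the 3 wild-type arrays, where wild type alone supplies the spread, 0 genes passed by limma and 1567 had an unadjusted p under 0.05. The endothelial list had a mean log2 fold change of −0.24 in that setting (camera with the preset correlation, adjusted p = 0.00178), but its call was lost with an estimated correlation even with all 6 arrays (adjusted p = 0.434). The sarcomere, mesothelium and cell cycle lists also kept their calls in that setting. With an estimated correlation over all 6 arrays their calls were lost as well (camera adjusted p = 0.434, 0.471 and 0.471). The other 13 of the 17 lists lost their calls with cryptorchid replicate 3 alone, among them the β-catenin, keratinocyte and macrophage lists.

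**Figure D3:**
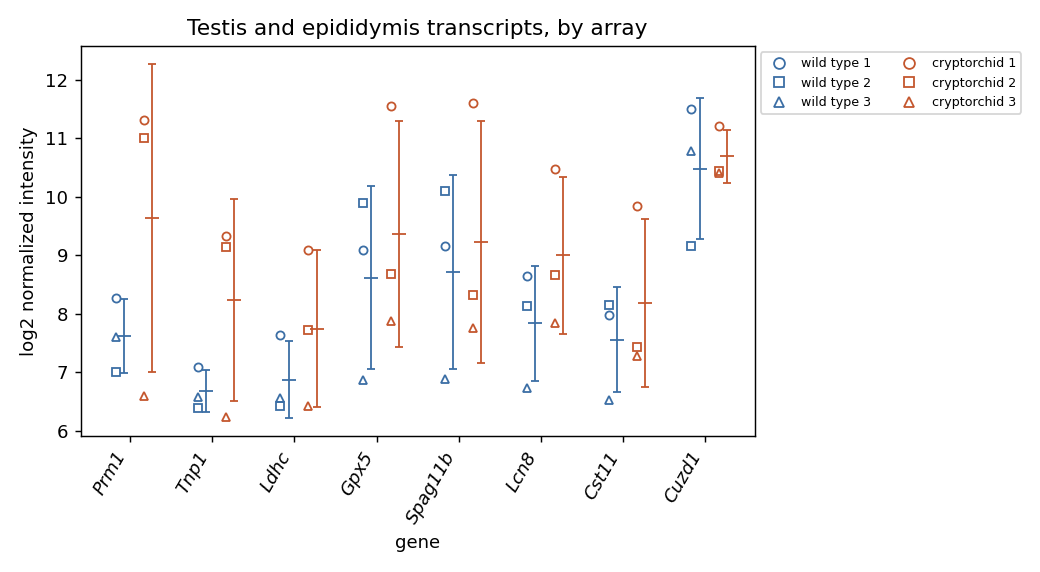
Log2 normalized intensity of testis genes (Prm1, Tnp1, Ldhc) and epididymis genes (Gpx5, Spag11b, Lcn8, Cst11, Cuzd1) on the 6 arrays, with the gene on the horizontal axis; open symbols are single arrays and bars are the group mean ± SD with n = 3. Prm1 reaches 11.32 and 11 on cryptorchid replicates 1 and 2 and 6.59 on replicate 3.

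In all, 17 of 44 lists shifted under camera with the preset correlation, 4 up and 13 down. With an estimated correlation 0 passed, and with fry 0 passed. Over 20 alternatives the call was also lost 9 times for cAMP and receptor signalling, 7 times for circadian clock genes, 5 times each for glycolysis and for macrophage markers, and 3 times for immediate early genes. It was lost 1 time, with cryptorchid replicate 3 alone, for the Notch (adjusted p = 0.0832), smooth muscle (0.0832), growth factor (0.0832), patterning (0.096), collagen and matrix (0.151) and myogenic regulator (0.171) lists.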

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

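The background offset of 16, the noise floor, cyclic loess, the stricter noise filter, the length trend and the single-array comparison were chosen after seeing the data. The count of calls depended on the setting. Without a background step (values under 1 set to 1) 3 genes changed (2 higher, 1 lower, 3 at least 2-fold) and 11 lists shifted. With offset 16 it was 13 (5 higher, 8 lower, 7 at least 2-fold), and with values under the noise threshold set to it 0 (0 higher, 0 lower, 0 at least 2-fold; 2596 at an unadjusted p under 0.05 by limma). With an intensity trend and robust estimation in limma's prior the last 2 settings gave 726 and 669, the latter with 113 of at least 2-fold; trend and robust estimation were not run apart. Array weights gave 932 (420 higher, 512 lower), and the ordinary per-gene test 0 (2529 at an unadjusted p under 0.05); the cause was not tested. Cryptorchid replicate 3 alone, assumed to vary like wild type, gave 0 (0 higher, 0 lower, 0 at least 2-fold; 1567 at an unadjusted p under 0.05) and 7 lists, with fewer samples. The replicate block gave 1436 (638 higher, 798 lower) and an Rxfp2 change of −0.64 with an adjusted p of 0.0296; over all alternatives this change ranged from −0.94 to −0.36 and its adjusted p from 0.0296 to 0.477. The labels state no pairing, and the replicate numbers were not taken as such. Deviations of same-numbered arrays correlated by 0.34, 0.06 and 0.27, and those of differently numbered arrays by −0.31 to 0.09. As deviations were taken from each group's mean and sum to 0 within it, these correlations are not independent of each other. Cryptorchid replicate 2 correlated best with wild-type replicate 3 (0.09), so a pairing stays open.

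Leaving out 1 array gave from 0 to 549 changed genes, 0 to 221 higher, 0 to 328 lower, 0 to 44 of at least 2-fold and 11 to 24 lists. An estimated correlation and fry both gave 0 lists. Of genes that did not pass, Ctnnb1 turned to −0.0069 with cyclic loess. Without single arrays, values that crossed 0 ranged from −0.038 to 0.11 for Ctnnb1, −0.034 to 0.32 for Rxfp1, −0.20 to 1.08 for Cst11, −0.35 to 1.49 for Gpx5 and −0.67 to 1.25 for Spag11b. With cryptorchid replicate 3 alone, Notch3 turned to 0.15, Hey1 to 0.052, Tnp1 to −0.44, Cst11 to −0.28, Prm1 to −1.03, Gpx5 to −0.75 and Spag11b to −0.95. Not run were neqc and detection p filters (no usable column), median or upper-quartile centring (the distributions already coincide) and a slide block (no slide used here). Signal over background limits what can be measured of dim genes.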

Other observations

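Chosen after the results were seen were the tests of changed genes and of unadjusted counts over splits, of how evenly the endothelial list moved, of the length trend, of the share of probes peaking on an array and of germ cell genes above noise, as well as the histone and ribosomal protein groupings and the genes H2ac18, H2ac19, H2ac21, Prm1, Tek, Emcn, Gpihbp1, Ly6c1 and Pdpn.

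Among the core histone families measured here, genes passed the test in the H2A family and not in the others. Of 12 H2A genes, 9 rose and 0 fell, with a median log2 fold change of 0.85 that ranged from 0.73 to 1.05 over the alternatives. As their probes were not compared, the 9 may not be separate changes. When 1 array was left out, 0 to 9 of the 12 passed, with 0 without cryptorchid replicate 1 and 0 without wild-type replicate 3. The exceptions were H2ac18 and H2ac19, with −0.37 ± 0.11 (SE) and −0.55 ± 0.14, and H2ac21, with 0.34 ± 0.13, none of which passed. Of 9 H2B genes, 0 passed and all 9 values were below 0, with a median of −0.20. The medians were 0.05 for 7 H3 genes, which turned to −0.07 once the length trend was removed, −0.06 with cryptorchid replicate 3 alone and −0.01 without wild-type replicate 3, and −0.11 for 9 H4 genes, and 0 of these passed.

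Both Lipa probes lay below the noise threshold on the wild-type arrays, with intensities from −7.21 to 0.889, and lay between 30.3 and 101 on the cryptorchid arrays. Of the 20 tested genes nearest to Lipa in chromosomal order, Lipo3 was the 1 that passed. The immediate early gene Egr1, which responds within minutes to handling of tissue, had a log2 fold change of −0.94 ± 0.40 (SE) and did not pass. In its list of 27 genes Nr4a2 fell by 0.55 ± 0.12 on the log2 scale, and the list shifted down (camera adjusted p = 0.00963), with an adjusted p = 0.471 with an estimated correlation. This list lay at −0.38 of mean log2 deviation on cryptorchid replicate 2 but at −0.02 and −0.005 on the other cryptorchid arrays and −0.005 on wild-type replicate 2, and without cryptorchid replicate 2 its adjusted p was 0.097. In the list of 14 circadian clock genes Cry2 fell by 0.46 ± 0.10, with −0.12 for its second probe. The clock list shifted down (camera adjusted p = 0.0348), with an adjusted p = 0.434 with an estimated correlation. Its mean log2 deviation overlapped between the groups, with −0.04 on wild-type replicate 1 and 0.01 on cryptorchid replicate 3. It was lowest on cryptorchid replicate 1, at −0.25. In the list of 26 cAMP and receptor signalling genes Adcy6 fell by 0.44 ± 0.10 (camera adjusted p = 0.0372), with an adjusted p = 0.471 with an estimated correlation.

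The endothelial and Notch lists both had a median below 0, and a candidate explanation is a lower share of endothelial cells in the cryptorchid sac. An even loss of such cells would lower alike all markers that only endothelium expresses. However, 5 of 19 list members brighter than the offset had a 95% interval wholly above the list median of −0.36. These were Tek, Emcn, Gpihbp1, Ly6c1 and Pdpn, the last of which mesothelium and lymphatic vessels also express. The intervals were not adjusted for the 19 members, and whether other cells of the sac express the 5 was not tested. The 21 Notch members not counted as endothelium-expressed had a median of −0.10 against −0.30 for the 11 that were; camera gave p = 0.0466 for the former, past the bound set beforehand, but the estimated correlation, required only after this value was seen, gave p = 0.119. The 11 endothelium-expressed members likewise passed camera with the preset correlation and did not pass with the estimated one. These calls therefore did not separate the endothelium-expressed members from the other 21. Size or brightness of the genes was tested with 10000 random sets matched on genomic length and intensity. Of their medians, 0% lay below that of the endothelial list, against a central range from −0.11 to 0.11. Random sets need not vary together as this list did (estimated correlation 0.168), so that range may be too narrow. A vessel share behind the Notch values stays open, as does a change within endothelial cells from the transgene or the undescended testis, which was not tested.

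Ribosomal protein genes had a median log2 fold change of 0.26 in cryptorchid against wild type over 58 genes, 10 of which rose and 1 fell, and of 0.226 to 0.286 over the alternatives, while 0 to 3 passed when 1 array was left out. Their mean deviation was below 0 on all 3 wild-type arrays (from −0.12 to −0.10) and above 0 on all 3 cryptorchid arrays (from 0.09 to 0.13). Of changed genes, 96 rose and 37 fell in the shortest of 5 equal groups by genomic length while 14 rose and 80 fell in the longest, but the medians over all genes of these groups were 0.02 and −0.03 (Spearman correlation of change with length −0.09). Size or brightness could underlie part of the shift, as 10000 matched sets had a median of 0.08. The ribosomal protein median lay above 100% of these sets, whose central range ran from −0.02 to 0.15. Random sets need not vary together as a gene family may, so that range may be too narrow. With the length trend removed, the ribosomal protein median was 0.226 and 6 of these genes passed, against 11 before. In that setting 508 of the 595 changed genes passed. Differences in RNA handling between the groups, for which no label was used here, and cell growth stay open as untested.

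Testis transcripts on cryptorchid replicates 1 and 2 may come from tissue carried over at dissection. Cryptorchid replicate 1, highest in Prm1, was also highest for 12 of 21 other germ cell genes, against 1 in 6 by chance (exact one-sided binomial p = 3.02e-05) or the 21.8% of all probes that peak there (p = 0.000451), and for 10 of the 15 above noise on any array, against the 22.7% of such probes that do so (p = 0.000343). Whether carry-over also made the changed genes was tested by ranking genes on 2 arrays per group and reading their sign on the held-out pair. For pairs with cryptorchid replicate 3, which had the lowest Prm1 of all arrays, the top 595 genes were compared with all genes. The same-sign share was 0.728, 0.896 and 0.931 with wild-type replicates 1, 2 and 3, against 0.587, 0.65 and 0.672 over all genes. Carry-over was set to give at most 0.6 and its absence over 0.8, so the lowest share lay between them. As all genes already gave near 0.6, passing that bound does not argue against carry-over. In the lowest pair, Prm1 intensity was higher in wild type (240.6) than in cryptorchid (29.3). Cryptorchid replicate 3 was chosen by Prm1 alone and was not lowest in Gpx5 (166.9, against 49.8 on wild-type replicate 3). The test therefore does not cover epididymis carry-over. Carry-over thus stays open. The count of changed genes was 14 and 7 without cryptorchid replicates 1 and 2, and 520 without cryptorchid replicate 3. However, it was also 0 without wild-type replicate 3, so these counts do not settle the question. A spread of testicular cells into the sac of cryptorchid males by another route was not tested.

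The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 595 changed genes and the highest other 2; 20 against 2 for changes of at least 2-fold; and 3093 against 1164 at an unadjusted p under 0.05. In each of these 3 counts the real split was the 1 with the highest value. For gene lists that shifted under camera, 2 of the 10 splits gave as many, with 17 in the real split and 22 in the highest other, which set wild-type replicate 1 with cryptorchid replicates 1 and 2.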
